A study of Mus musculus with 6 samples.

How the data were processed

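The 6 libraries came from mouse neurospheres of ventricular-subventricular zone precursors carrying NestinCreERT2 and the RiboTag allele, precipitated with anti-HA (3 libraries) or anti-IgG (3 libraries). Per the labels' protocols, cDNA was made with the SMART-Seq v4 Low Input kit and libraries with the Nextera XT kit, which do not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. Groups and experiment numbers were taken from the sample titles. The experiments are taken as separate neurosphere preparations because the titles number them; the labels do not say how many animals each came from.

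Per the submitters' processing notes, the tools were FastQC 0.11.5, Trim Galore 0.5.0, STAR 2.6.0c, HTSeq 0.6.1p2 and DESeq2 1.26.0, with genome build mm10. The annotation and the treatment of reads that map to several places are not given in the sources used here. Per the file headers, the authors deposited FPKM (fragments scaled by gene length and library size) for each library. The same deposited table holds a mean signal per gene over libraries, a log2 fold change of HA over IgG with its standard error on the log2 scale, a test statistic (a score) and a p-value with its adjusted p-value. The authors' adjusted p-values equalled the Benjamini-Hochberg adjustment over all 33380 genes. Their log2 fold changes lay closer to the mean of the 3 within-experiment log ratios (median difference 0.0213, over the 12265 genes above 0.5 FPKM in all libraries) than to the ratio of group means (0.0314). Their mean signal was above 0 for 2 genes listed at 0 in all 6 libraries, which these 6 libraries alone cannot give, so it was not used here. The set of libraries behind the authors' scaling of the FPKM, fold changes and calls is thus unknown.

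The values are not counts, so no count model was used. FPKM of the same gene in different libraries were ratios of whole numbers times a constant per library, within a relative tolerance of 1e-09, for 33378 genes, and 98.0% of the gene lengths that follow were whole numbers within 0.01 bp when mt-Rnr1 was set to its 955 bp. This gave the read totals, as lower limits, since a common factor within a gene cannot be seen. The FPKM were scaled by a size factor and not by total reads: relative to IgG 1, reads per unit of scaling were 1.33, 1.54 and 1.90 in HA 1 to 3 and 1.08 and 1.06 in IgG 2 and IgG 3. Fold changes therefore depend on that scaling.

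HA and IgG were compared with limma-trend (limma 3.58.1, R 4.3.3) on log2(FPKM + 1), with the antibody as the only term and Benjamini-Hochberg adjustment over the tested genes, with adjusted p below 0.05 as the threshold. A fold change is on the log2(FPKM + 1) scale and understates the change of low genes. The design, the gene lists and the rule for named genes were fixed before the data were examined. The design named a count test and this test as its replacement where no counts were given. The filter of at least 1 FPKM in at least 3 libraries was set once the unit was known and before any test, and minimum levels planned in CPM were applied in FPKM. Printed values are mean ± SD of FPKM (n = 3) and log2 fold change ± SE. Same-numbered HA and IgG libraries deviated from their group means together across genes (correlations 0.60, 0.60 and 0.71 for experiments 1, 2 and 3), so the numbers pair the samples, and the fit with the experiment as a block is given beside results whose call or count it changed. That fit has 2 residual degrees of freedom, against 4 without the block.

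Of the 26 gene lists, 23 had at least 5 measured members. They were tested with camera at a preset correlation of 0.01, with adjustment over the 23 lists. Camera asks whether a list lies higher or lower than the other tested genes. Genes were named by a fixed rule: Rpl22, Rpl22l1, Eif4enif1, Nes and Malat1 always; the 10 largest increases and the 10 largest decreases among genes past the threshold with a mean of at least 10 FPKM and the same direction in all 3 experiments; and up to 4 members per list, the 2 with the smallest p and the 2 with the highest mean. Predicted genes (26 higher and 22 lower that met the other criteria) were passed over. Together 104 genes met the rule, and the choice of those given in full was made after their values were seen. Of the 33380 identifiers, 30937 matched the gene name table, and 12303 of the 13172 tested genes matched a RefSeq gene by identifier or symbol, from which gene classes and coordinates (GRCm38.p6, the assembly of mm10) were taken.

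The gene test was tested on simulated data with the library depths of these libraries, 13172 genes with 100 genes changed per fold size. All genes were given the same log2 spread, the median residual SD of 0.231 and a spread between experiments of 0.299. Real genes differ in spread, so the results hold for this equal-spread case. It recovered 8% of genes changed 2-fold and 100% of those changed 4-fold, with 2 false calls. The blocked fit recovered 87% and 100%, with 28 false calls, a larger share of its calls than the threshold of 0.05 aims at. Blocked calls in these data may likewise hold more false ones than the threshold states. In the simulated HA versus IgG comparison, 1% of 200 unchanged lists of 40 genes passed an unadjusted p of 0.05 in camera. Genes were drawn independently of each other there, so this does not test camera where genes of a list are correlated.

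Alternatives were the block, total-read and median-ratio scaling, scaling to mitochondrially encoded protein genes, limma-voom on the recovered reads, no filter and a stricter filter, a pseudocount of 0.1, a 2-fold minimum, and fits without each library or experiment; for lists, an estimated correlation and fry. The planned count test with its own scaling was not run. Figures were drawn with matplotlib 3.10.9.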

Results

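RNA bound to tagged ribosomes was compared with the RNA recovered by a control antibody from the same kind of cells. The cells were neurospheres, floating colonies grown from precursor cells of the mouse ventricular-subventricular zone, a germinal zone of the postnatal forebrain. They carried RiboTag, an allele of Rpl22 in which Cre recombinase adds a hemagglutinin (HA) tag to a protein of the large cytosolic ribosomal subunit. Cre came from a Nestin-driven transgene that acts only after tamoxifen. Neurospheres grew for 5 days, were given tamoxifen, and were lysed 2.5 days later, at day 7.5. RNA was precipitated with an anti-HA antibody (HA) or with anti-IgG (IgG) in each of 3 experiments, which gave 3 HA and 3 IgG libraries. The series concerns 4E-T, a protein of cytoplasmic P-bodies that is encoded by Eif4enif1. The question this contrast addresses is which RNAs had a higher or lower relative level in the anti-HA precipitate than in the IgG background. FPKM are scaled per library, so they do not show how much RNA each precipitation recovered.

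The table held FPKM for 33380 genes in each library. The reads behind these values, recovered from their exact ratios, came to at least 29446971, 35492703 and 82846542 reads in HA 1, HA 2 and HA 3, and to at least 13067493, 35174738 and 56294388 in IgG 1, IgG 2 and IgG 3. IgG 1 was thus the shallowest library and HA 3 the deepest. The tests covered the 13172 genes with at least 1 FPKM in at least 3 libraries.

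Compared with IgG libraries, HA libraries had higher FPKM for many abundant protein-coding genes. They had far lower FPKM for mitochondrially encoded genes, and lower FPKM for many noncoding RNA genes. Of the 13172 genes, 1148 were higher and 676 lower in HA (limma-trend, adjusted p below 0.05), and 11348 did not pass. With the experiment as a block, 4541 were higher and 1919 lower. Calls followed the level of the gene. Of the 1704 genes with a mean of at least 50 FPKM, 402 were higher and 22 lower, or 1231 and 45 with the block. Of the 4529 genes with a mean under 5 FPKM, 32 were higher and 444 lower, or 485 and 1287 with the block. Across genes, which are not independent replicates, the log2 fold change had a Spearman correlation of -0.21 with exonic length. The correlation was 0.58 with the mean level, which was over all 6 libraries and so held the HA values too. By class, 41 of 73 snoRNAs, 18 of 34 snRNAs, 24 of 48 microRNA genes and 84 of 368 long noncoding RNAs were lower in HA, against 280 of 11061 protein-coding genes, which also held 1105 of the higher calls. Of the microRNA genes 2 were higher. These are counts of annotated genes. Whether reads at the snoRNA, snRNA and microRNA genes came from the mature RNAs was not tested. With the block, 72 snoRNAs, 31 snRNAs, 40 microRNA genes, 186 long noncoding RNAs and 1094 protein-coding genes were lower, and 4161 protein-coding genes were higher. By two-sided Fisher's exact tests, lower calls made up a larger share of snoRNAs (p = 1.22e-44, adjusted p = 1.83e-44) and long noncoding RNAs (p = 2.16e-49, adjusted p = 6.49e-49) than of protein-coding genes, and did so with the block too (adjusted p = 3.68e-70 and 2.63e-81). For pseudogenes the share was larger without the block by Fisher's exact test (30 lower and 10 higher of 626, p = 0.00186, adjusted p = 0.00186) but did not pass with it (75 lower and 212 higher, adjusted p = 0.0999), and their median log2 fold change of 0.34 was near that of protein-coding genes, 0.35. The Benjamini-Hochberg adjustment was over these 3 classes, and genes are not independent replicates. Genes near 0 in HA could also meet the filter through the 3 IgG libraries alone, and genes near 0 in IgG through the 3 HA libraries. More genes had at least 1 FPKM in IgG 1 to 3 (19064, 13057 and 14167) than in HA 1 to 3 (12393, 12091 and 12588). The filter could thus let in more genes near 0 in HA than near 0 in IgG. That favours lower calls among genes of low level, where 444 of the 676 lay. These tests therefore cannot tell gene class from level and filter.

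The split between higher and lower depended on how libraries were scaled. The median log2 fold change of the tested genes was 0.27 as deposited and -0.21 after scaling to total reads, which gave 172 higher and 1258 lower genes, or 1362 and 3824 with the block. Leaving out 1 library also moved the unblocked counts. They were 1372 higher and 675 lower without HA 1, 1 and 35 without HA 2, 250 and 199 without HA 3, 2 and 54 without IgG 1, 243 and 467 without IgG 2, and 21 and 89 without IgG 3. With both libraries of an experiment left out, the blocked fit gave 3870 and 1761 (experiment 1), 4110 and 1583 (experiment 2), and 3193 and 1499 (experiment 3). Those blocked fits kept all 1148 higher calls in each case, and 676, 675 and 676 of the lower calls. They reuse libraries behind those calls and have fewer residual degrees of freedom than the full blocked fit. Their calls thus lean on the spread pooled across genes. Without the block, the counts were 0 higher and 21 lower (experiment 1 left out), 0 and 0 (experiment 2), and 17 and 58 (experiment 3). Of the 52 named genes past the threshold, 47 passed without HA 1, 10 without HA 2, 38 without HA 3, 11 without IgG 1, 35 without IgG 2 and 19 without IgG 3. After scaling to total reads 39 passed, the others being Lars2, Hopx, Sox1, Glul, Edc3, Cnot11, Ubr7, Mmp15, Nrarp, Sufu, Ctnnb1, Psmd5 and Zfp207 (adjusted p from 0.0523 to 0.330), and all 52 kept their direction.

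**Figure D1:**
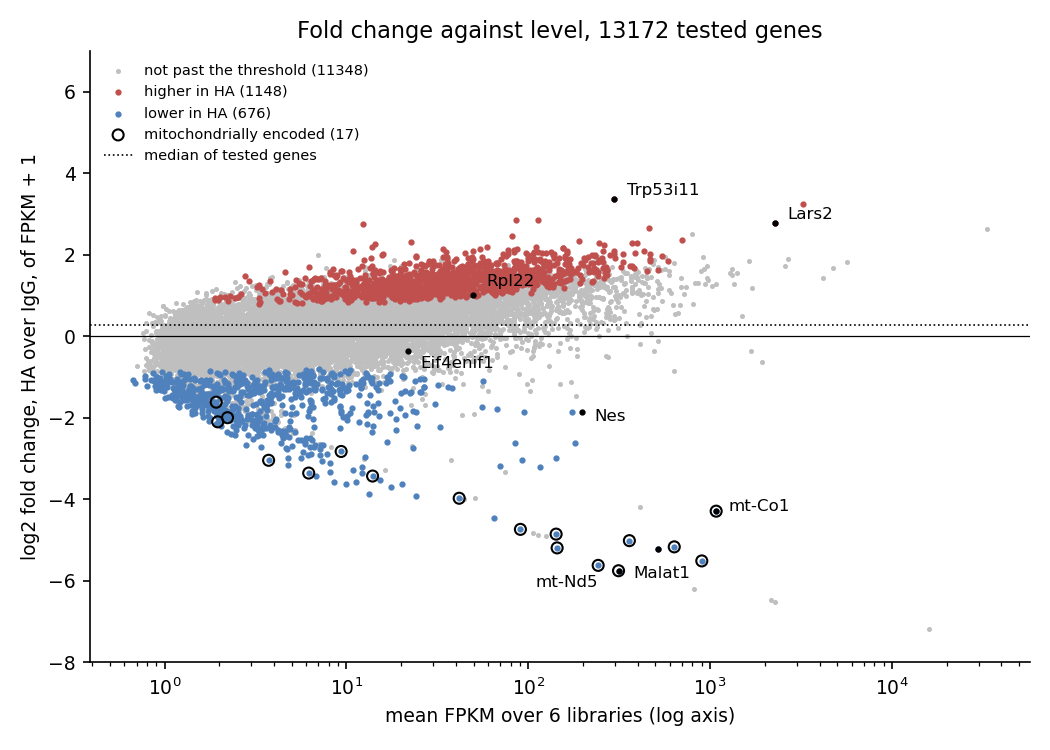
Log2 fold change (HA over IgG, of FPKM + 1) against mean FPKM over the 6 libraries, on a log axis, for the 13172 tested genes. Red points are the 1148 genes higher in HA, blue points the 676 lower, open circles the 17 mitochondrially encoded genes, and the dotted line is the median of 0.27. Labelled black points are named genes, fold changes lie higher at higher level, and Malat1 (-5.22) and mt-Nd5 (-5.75) lie far below most genes of similar level.

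The tagged gene itself, Rpl22 (chromosome 4, 152324436 to 152334082, GRCm38), measured 66.5 ± 15.8 FPKM in HA and 33.4 ± 12.3 in IgG (SD, n = 3 each), a log2 fold change of 1.02 ± 0.37 (SE). It did not pass over all genes (adjusted p = 0.0860) and passed with the block (adjusted p = 0.00490). After scaling to total reads its log2 fold change was 0.45 (limma-trend without the block, adjusted p = 0.351). Rpl22l1, the paralog of Rpl22, measured 47.9 ± 24.4 FPKM in HA and 33.6 ± 9.64 in IgG (adjusted p = 0.448), and its log2 fold change was 0.43 as deposited and -0.14 after scaling to total reads. Eif4enif1 (chromosome 11, 3202343 to 3244588) measured 18.7 ± 3.15 FPKM in HA and 24.7 ± 5.23 in IgG, with a log2 fold change of -0.37 ± 0.27 and an adjusted p of 0.338. After scaling to total reads the log2 fold change of Eif4enif1 was -0.93 (limma-trend without the block, adjusted p = 0.0679). Neither gene passed with the block (adjusted p = 0.254 for Rpl22l1 and 0.149 for Eif4enif1). Nes, the source of the Cre driver and an intermediate filament gene of neural precursors, stood at 51.7, 33.2 and 43.5 FPKM in HA 1 to 3, and at 88.2, 46.8 and 917.8 in IgG 1 to 3. Its adjusted p was 0.176, and 0.0238 with the block, as lower in HA. The high IgG mean of Nes rested on IgG 3.

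**Figure D2:**
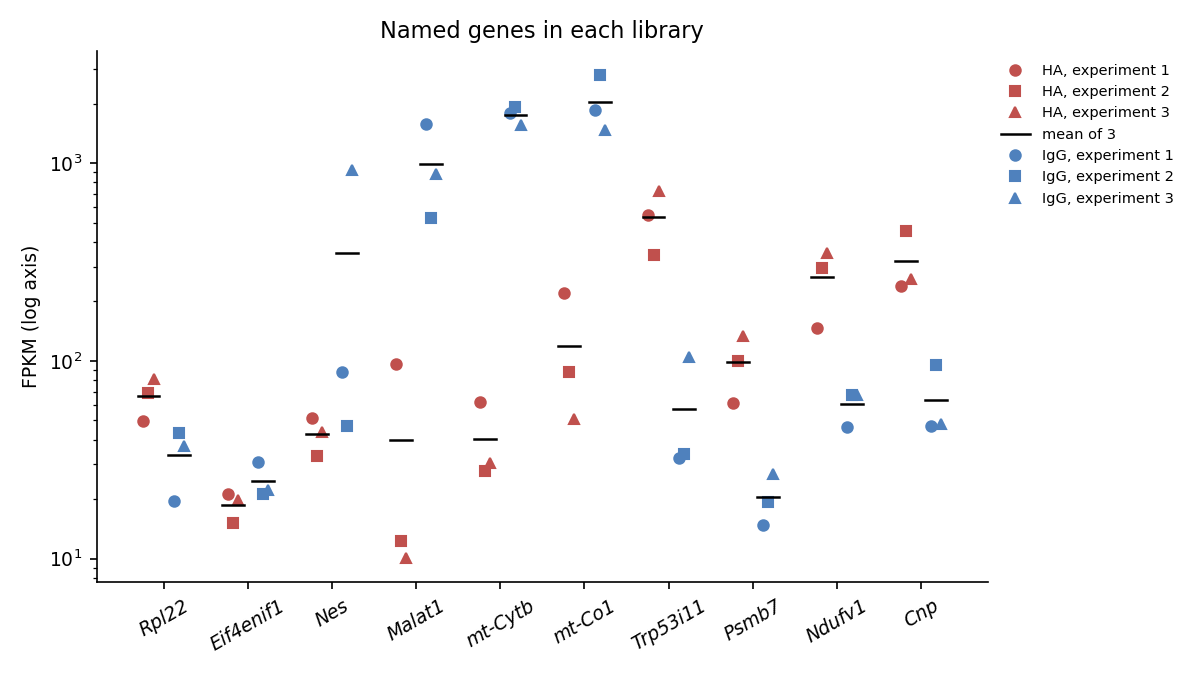
FPKM of 10 named genes in each library, on a log axis, with HA in red, IgG in blue, a marker shape per experiment and a black line at the mean of 3. Malat1, mt-Cytb and mt-Co1 lie lower in all HA libraries than in any IgG library, whereas Trp53i11, Psmb7, Ndufv1 and Cnp lie higher.

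The 10 genes with the largest decreases in HA were 9 mitochondrially encoded genes and Malat1. mt-Nd5, which encodes a subunit of respiratory complex I, measured 11.7 ± 9.51 FPKM in HA and 616 ± 278 in IgG, a log2 fold change of -5.75 ± 0.53 (adjusted p = 0.00247). mt-Nd6 (-5.62 ± 0.54), mt-Nd2 (-5.19 ± 0.37), mt-Nd1 (-5.17 ± 0.54) and mt-Nd4 (-4.85 ± 0.46) encode further complex I subunits. mt-Cytb, the cytochrome b gene, stood at 62.0, 27.7 and 30.6 FPKM in HA 1 to 3 and at 1790, 1931 and 1560 in IgG 1 to 3 (log2 fold change -5.51 ± 0.43, adjusted p = 0.00169). mt-Co1, a cytochrome c oxidase gene, had the smallest of these decreases, -4.29 ± 0.60 (adjusted p = 0.0155). The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 had log2 fold changes of -5.01 ± 0.42 and -4.74 ± 0.52. Malat1, a nuclear long noncoding RNA (chromosome 19, 5795690 to 5802672, GRCm38), measured 39.8 ± 49.6 FPKM in HA and 995 ± 529 in IgG, a log2 fold change of -5.22 ± 0.80 (adjusted p = 0.0203). Without HA 1, which held the highest HA value of both, Malat1 had a log2 fold change of -6.22 and mt-Nd1 of -5.78, and without IgG 3 mt-Rnr1 had -4.14. All 10 passed with the block and after scaling to total reads. 8 of the 10 passed without HA 2 or without IgG 1, 9 without IgG 3, and all 10 without any other single library. Malat1 was among those that did not pass in each of these 3 cases (adjusted p = 0.0938, 0.0813 and 0.0512). The mitochondrial genome has near-identical copies in nuclear chromosomes, and mt-Nd5 and mt-Nd6 overlap at their ends on opposite strands, so reads of these genes can be shared.

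As groups, 16 of the 17 measured mitochondrially encoded genes were lower in HA (17 adjusted over the list alone and 17 with the block), with a median log2 fold change of -4.29. The list lay lower than the other genes (camera, adjusted p = 9.84e-24), but this did not hold with an estimated correlation (adjusted p = 0.122). Its 8 measured protein genes were all lower, over all genes, adjusted over the list alone and with the block (camera adjusted p = 8.5e-14, and adjusted p = 0.234 with an estimated correlation). The summed FPKM of the protein genes was 237 ± 163 in HA and 6695 ± 1371 in IgG (SD, n = 3 each), and the IgG sum was 15.7, 50.9 and 41.9 times the HA sum in experiments 1, 2 and 3. Of 26 measured nuclear and long noncoding RNAs, 16 were lower and none was higher (19 lower adjusted over the list alone and 21 lower with the block), with a median of -1.33. This list also lay lower (camera adjusted p = 2.67e-15, and adjusted p = 0.157 with an estimated correlation). Its members included Firre, an X-linked nuclear RNA (log2 fold change -2.72 ± 0.38, adjusted p = 0.0155), Snhg20 (-2.67 ± 0.34, adjusted p = 0.0101) and Gas5 (-1.79 ± 0.28, adjusted p = 0.0213), the latter 2 being host RNAs of snoRNAs. All 17 mitochondrially encoded genes lay below 0 under deposited, total-read and median-ratio scaling, as did 25, 26 and 25 of the 26 nuclear and long noncoding RNAs.

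The 10 genes with the largest increases in HA ranged from a log2 fold change of 2.30 to 3.37. Trp53i11, a p53-inducible membrane protein gene on chromosome 2 (93187349 to 93201757, GRCm38), led with 536 ± 187 FPKM in HA and 56.9 ± 41.2 in IgG, a log2 fold change of 3.37 ± 0.53 (adjusted p = 0.0210). Trappc2l, a subunit of a vesicle tethering complex, measured 150 ± 42.5 FPKM in HA and 20.2 ± 6.29 in IgG (log2 fold change 2.85 ± 0.36, adjusted p = 0.00910). Mpst, a mitochondrial sulfurtransferase (2.75 ± 0.45), Raly, an RNA-binding protein (2.46 ± 0.47), Cnp, a myelin-associated phosphodiesterase (2.33 ± 0.43), Gpd1, a glycerol phosphate dehydrogenase (2.32 ± 0.36), and H2afv, a histone variant (2.30 ± 0.41), also passed. Mir6236 (3.24 ± 0.69), Mir6240 (2.84 ± 0.47) and Lars2, the mitochondrial leucyl-tRNA synthetase (2.78 ± 0.71), completed the 10. Mir6236 reached 5875 ± 3579 FPKM and Lars2 4016 ± 2956 in HA, where HA 1 held the highest value of each. Reads at Mir6236, Mir6240 and Lars2 may come from repeated sequence and not from the genes' own transcripts, a question that stays open below. All 10 passed with the block, and 9 passed after scaling to total reads, Lars2 being the exception (adjusted p = 0.0692). Of the 10, 9 passed without HA 1 or HA 3, 8 without IgG 2, 6 without IgG 3, and 1 without HA 2 or without IgG 1. No gene among the top 20 changed sign in any of these fits.

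Genes of the nuclear-encoded respiratory chain, the proteasome and the mitochondrial and cytosolic ribosomes lay higher in HA as groups. Of 36 measured proteasome subunits, 13 were higher and none lower, with a median of 1.28 and all 36 above 0. Psmb7, a core particle subunit, measured 98.3 ± 36.7 FPKM in HA and 20.4 ± 6.10 in IgG (log2 fold change 2.18 ± 0.37, adjusted p = 0.0255), and Psmd5 had 1.31 ± 0.25 (adjusted p = 0.0290). Adjusted over the list alone 21 were higher, and 33 with the block (camera adjusted p = 3.71e-07, and adjusted p = 0.922 with an estimated correlation). Of 93 nuclear-encoded respiratory chain genes, 16 were higher and none lower, with a median of 1.21, led by the complex I subunits Ndufv1 (2.05 ± 0.41, adjusted p = 0.0302) and Ndufa6 (1.95 ± 0.41, adjusted p = 0.0328). Adjusted over the list alone 42 were higher, and 78 with the block (camera adjusted p = 6.07e-08, and adjusted p = 0.922 with an estimated correlation). Atp5b, an ATP synthase subunit at 2578 ± 846 FPKM in HA and 692 ± 128 in IgG, passed with the block but not without it (adjusted p = 0.0601 without it and 0.00416 with it).

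Of 81 mitochondrial ribosomal protein genes, 16 were higher and none lower, with a median of 1.11, among them Mrpl4 (1.63 ± 0.34) and Mrps27 (1.59 ± 0.31). Adjusted over the list alone 37 were higher, and 66 with the block (camera adjusted p = 3.54e-08, and adjusted p = 0.922 with an estimated correlation). Of 85 cytosolic ribosomal protein genes, many of which have processed pseudogenes that can share reads, 4 were higher and none lower, with a median of 0.92. Rpl30 (1.89 ± 0.34, adjusted p = 0.0282) and Rpl5 (1.81 ± 0.40, adjusted p = 0.0333) passed. Rps2, at 1213 ± 63.9 FPKM in HA and 507 ± 171 in IgG, passed with the block but not without it (adjusted p = 0.0985 without it and 0.0139 with it). Adjusted over the list alone 1 was higher, and 45 with the block (camera adjusted p = 0.0012, and adjusted p = 0.954 with an estimated correlation). Of 39 translation initiation and elongation factors, 8 were higher and none lower, with a median of 0.88. Eif4a1, the RNA helicase of the cap-binding complex, measured 625 ± 175 FPKM in HA and 152 ± 46.0 in IgG (2.04 ± 0.43, adjusted p = 0.0328), whereas Eef1a1, at a mean of 1724 FPKM in HA and 1258 in IgG, did not pass (log2 fold change 0.50 ± 0.62, adjusted p = 0.578, and -0.09 after scaling to total reads). Adjusted over the list alone 14 were higher, and 22 with the block (camera adjusted p = 0.0012, and adjusted p = 0.922 with an estimated correlation). All 5 lists had medians above 0 after scaling to total reads, between 0.31 and 0.70. These genes are abundant, with list medians of 39.0 to 193 FPKM against 9.24 over all tested genes, and the level trend described above runs the same way. Among genes with at least 10 FPKM in at least 3 libraries, the cytosolic ribosomal protein and translation factor lists no longer passed (camera adjusted p = 0.764 and 0.355).

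**Figure D3:**
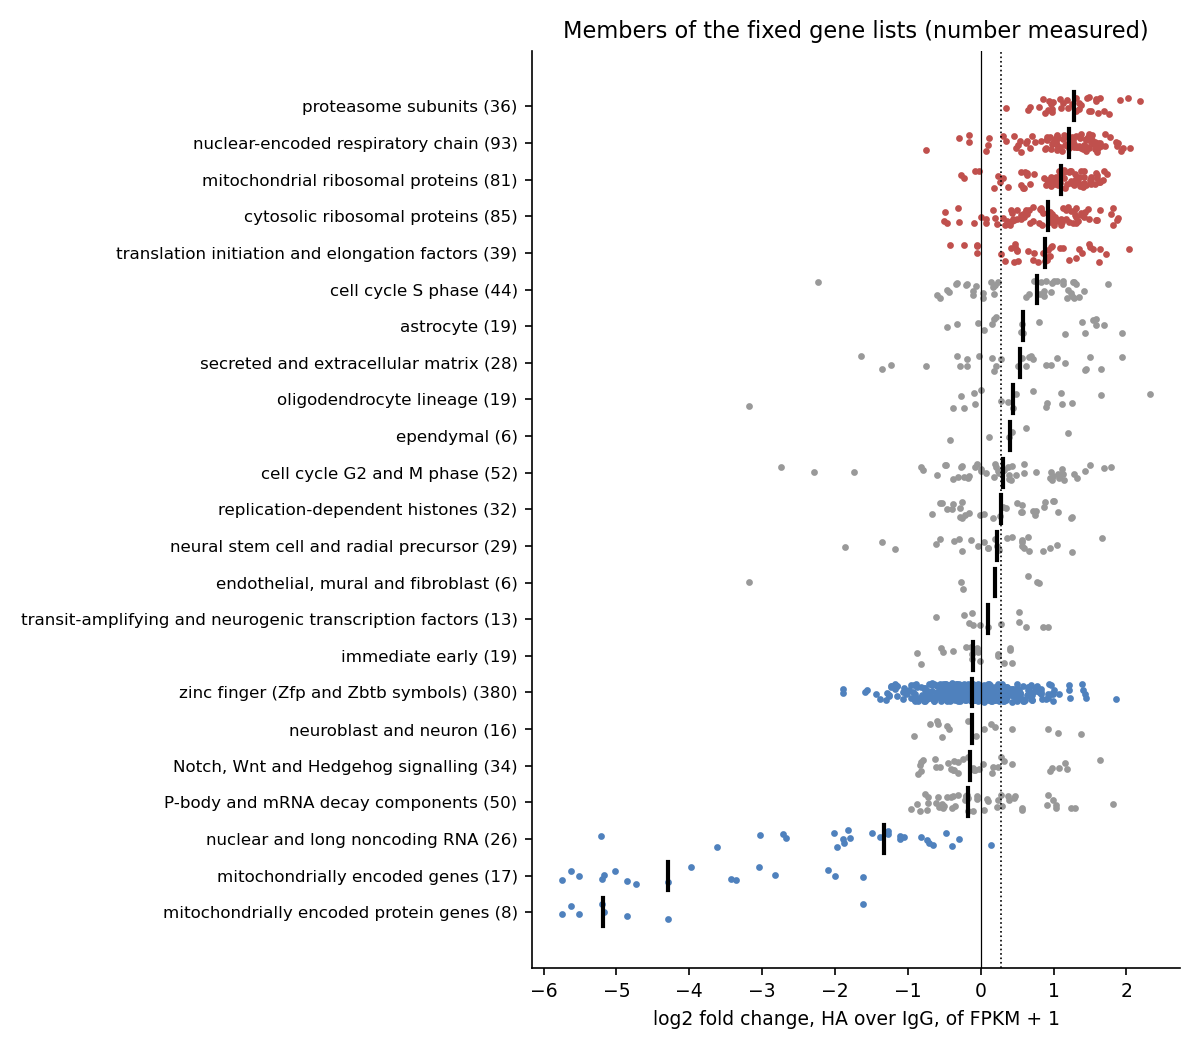
Log2 fold change (HA over IgG, of FPKM + 1) of each measured member of the 23 fixed lists with at least 5 measured members, with black bars at list medians. Red lists passed as higher and blue lists as lower (camera with a preset correlation), and the dotted line is the median of all tested genes, 0.27. Proteasome subunits have the highest median, 1.28, and mitochondrially encoded protein genes the lowest, -5.18.

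Zinc finger genes, largely DNA-binding regulators, lay lower. Of 380 measured, 9 were higher and 21 lower (none adjusted over the list alone, and 49 and 83 with the block), with a median of -0.12, against 0.27 for all tested genes (camera adjusted p = 5.11e-05, and adjusted p = 0.922 with an estimated correlation). Zfp970 (-1.89 ± 0.34, adjusted p = 0.0282) and Zfp280c (-1.56 ± 0.30, adjusted p = 0.0287) were lower, whereas Zfp207, at 147 ± 20.9 FPKM in HA and 53.7 ± 11.6 in IgG, was higher (1.45 ± 0.32, adjusted p = 0.0328). Components of P-bodies and mRNA decay, the compartment in which 4E-T resides, did not move together. Of 50 measured, 5 were higher and none lower, over all genes and adjusted over the list alone, and with the block 9 were higher and 13 lower. The median was -0.18 and the list did not pass (camera adjusted p = 0.0917). It did pass as lower after scaling to total reads (adjusted p = 0.0201, median -0.65) and among genes with at least 10 FPKM in at least 3 libraries (camera adjusted p = 0.00500). Both calls used the preset correlation, and an estimated correlation gave the list an adjusted p of 0.922 on the deposited scale (camera). Edc3, an enhancer of decapping, measured 18.1 ± 1.08 FPKM in HA and 6.78 ± 0.947 in IgG (1.30 ± 0.23, adjusted p = 0.0282), and Cnot11, a subunit of a deadenylase complex, had 1.25 ± 0.24 (adjusted p = 0.0287). Lsm4 passed with the block but not in the fit without it (adjusted p = 0.0530 without it and 0.000761 with it).

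Markers of neural stem cells and of other cell types mostly did not pass. Of 29 stem cell and radial precursor genes, 2 were higher and none lower (none adjusted over the list alone, and 8 higher and 5 lower with the block). These were Hopx (27.3 ± 9.68 FPKM in HA and 10.4 ± 1.87 in IgG, adjusted p = 0.0423) and Sox1 (0.85 ± 0.24, adjusted p = 0.0482), and neither passed after scaling to total reads (adjusted p = 0.179 and 0.330). Fabp7, a radial precursor gene at 7269 ± 3794 FPKM in HA and 2195 ± 721 in IgG, and Vim, at 603 ± 281 and 304 ± 163, did not pass without the block (adjusted p = 0.169 and 0.224) and passed with it (adjusted p = 0.0215 and 0.0180). None of 13 transit-amplifying and neurogenic transcription factors and none of 16 neuroblast and neuron genes passed, over all genes or adjusted over the list alone. With the block 4 of the former were higher and 1 lower, and 3 of the latter were higher and 2 lower. Of 19 astrocyte genes, 4 were higher (4 adjusted over the list alone and 11 with the block), including Aldoc, at 327 ± 71.2 FPKM in HA and 100.5 ± 21.2 in IgG (1.69 ± 0.37, adjusted p = 0.0328), and Glul, the glutamine synthetase gene (1.39 ± 0.29, adjusted p = 0.0319). The astrocyte list did not pass (camera adjusted p = 0.133), and did after scaling to total reads (adjusted p = 0.0224, median 0.16). Both values used the preset correlation, and an estimated one gave an adjusted p of 0.954 on the deposited scale (camera). Of 19 oligodendrocyte lineage genes, 1 was higher (Cnp) and 1 lower, over all genes and adjusted over the list alone, and 7 were higher and 1 lower with the block. The lower gene was Cspg4, a proteoglycan gene of oligodendrocyte precursors and pericytes, which measured 8.55 ± 2.29 FPKM in HA and 131 ± 145 in IgG (-3.18 ± 0.71, adjusted p = 0.0336). It stood at 28.1, 69.5 and 296.6 FPKM in IgG 1 to 3. Without IgG 3 its log2 fold change was -2.27 and it did not pass, nor did it without HA 2, HA 3 or IgG 2, and without IgG 1 it was -3.95. Olig1, at 2013 ± 1004 FPKM in HA and 631 ± 280 in IgG, did not pass without the block (adjusted p = 0.0911) and passed with it (adjusted p = 0.00533).

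None of 6 measured ependymal genes passed (2 higher with the block). Of 6 endothelial, mural and fibroblast genes, Cspg4 alone was lower and none was higher (2 higher and 1 lower adjusted over the list alone, and 3 and 1 with the block). Only 3 of 20 microglia genes, 1 of 12 choroid plexus and erythroid genes and 2 of 1204 olfactory and vomeronasal receptor genes were measured, too few for a list test. None of these 6 genes passed, and with the block 1 microglia gene and 1 receptor gene were lower. Camera adjusted p-values were 0.870 for stem cell, 0.938 for transit-amplifying, 0.235 for neuron, 0.814 for oligodendrocyte, 0.765 for ependymal and 0.878 for endothelial genes. The medians of the stem cell, transit-amplifying and endothelial lists were above 0 as deposited (0.23, 0.09 and 0.20) and below 0 after scaling to total reads (-0.33, -0.46 and -0.15). Camera placed these 3 lists and the histone list lower than the other genes, without passing, although their medians were above 0. The endothelial list had a mean of -0.25 beside its median of 0.20, and the P-body list a mean of 0.01 beside its median of -0.18. Among genes with at least 10 FPKM in at least 3 libraries, the stem cell list passed as lower (camera adjusted p = 0.0242). That call used the preset correlation, and an estimated one gave an adjusted p of 0.954 with the main filter (camera).

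Among growth and signalling genes, single members passed in both directions. Of 44 S phase genes, 5 were higher and 1 lower (9 and 1 adjusted over the list alone, and 24 and 3 with the block; camera adjusted p = 0.161). The lower one was Atad2, a chromatin-bound ATPase (-2.23 ± 0.41, adjusted p = 0.0287), and Ubr7 (1.35 ± 0.25, adjusted p = 0.0287) was among the higher. Of 52 G2 and M phase genes, 4 were higher and 3 lower, over all genes and adjusted over the list alone, and 17 and 5 with the block (camera adjusted p = 0.814). The mitotic kinase Nek2 was higher (41.1 ± 0.696 FPKM in HA and 13.9 ± 1.58 in IgG, adjusted p = 0.0225) and the mitotic kinesin Kif20b lower (-1.74 ± 0.37, adjusted p = 0.0328). Of 34 Notch, Wnt and Hedgehog genes, 3 were higher and none lower (2 higher adjusted over the list alone, and 6 higher and 8 lower with the block; camera adjusted p = 0.0917). The 3 were Nrarp, a Notch feedback inhibitor (1.64 ± 0.26, adjusted p = 0.0225), Sufu, a repressor of Hedgehog signalling (0.98 ± 0.22, adjusted p = 0.0331), and Ctnnb1, which encodes beta-catenin (1.19 ± 0.33, adjusted p = 0.0473). None of the 3 passed after scaling to total reads (adjusted p = 0.0523, 0.238 and 0.215). Of 28 secreted and extracellular matrix genes, 2 were higher and 1 lower (3 and 2 adjusted over the list alone, and 12 and 4 with the block; camera adjusted p = 0.775), with Mmp15, a membrane metalloproteinase, higher (1.44 ± 0.34) and the laminin gene Lama5 lower (-1.23 ± 0.27). None of 19 immediate early genes (camera adjusted p = 0.0917) and none of 32 replication-dependent histone genes (camera adjusted p = 0.674) passed, over all genes or adjusted over the list alone. With the block, 2 of the former were lower, and 9 of the latter were higher and 2 lower. The immediate early list passed as lower after scaling to total reads (camera adjusted p = 0.0392), without experiment 1 (adjusted p = 0.0471) and with the 10 FPKM filter (adjusted p = 0.00160), as did the Notch, Wnt and Hedgehog list with that filter (adjusted p = 0.0242). These calls used the preset correlation. An estimated one gave adjusted p-values of 0.954 and 0.922 for the 2 lists in the main setting (camera). Medians of the G2 and M, matrix and histone lists were above 0 as deposited and below 0 after scaling to total reads (-0.26, -0.02 and -0.13).

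In each experiment the IgG library also held more low-level signal than the HA library at olfactory and vomeronasal receptor genes, though HA 1 lay close to IgG 2. The 1204 olfactory and vomeronasal receptor genes, which are typically silent outside sensory epithelia, summed to 79.3, 5.52 and 9.21 FPKM in HA 1 to 3 and to 749, 89.3 and 167 in IgG 1 to 3. Their share above 0 was 85.0%, 14.6% and 20.7% in HA and 100%, 88.0% and 99.3% in IgG, although IgG 1 was the shallowest library and HA 3 the deepest. In the authors' deposited table, 2318 of the 33380 genes were higher and 9863 lower at an adjusted p below 0.05, and 8736 of those lower genes were not among the 13172 tested here. Of the 1148 higher and 676 lower genes found here, the authors' deposited table also called 1106 higher and 611 lower, and it called none of them in the other direction.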

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

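The limits are the 3 libraries per group and the scaling. All 52 named genes past the threshold kept their sign, and their calls, with the replicate block, median-ratio factors, limma-voom and pseudocount 0.1. With scaling to total reads all 52 kept their sign and 39 passed. Without HA 1, HA 2, HA 3, IgG 1, IgG 2 and IgG 3 in turn, all kept their sign and 47, 10, 38, 11, 35 and 19 passed. Named genes were not run with the other filters or with mitochondrial scaling, where 542 of the 1824 calls turned around. The spread between experiments stays in the residuals of the unblocked fit, which recovered 8% of simulated 2-fold changes against 87% with the block. False calls in that simulation were 2 without the block and 28 with it. The cause of the shifts below was not tested unless named.

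The 1824 genes past the threshold became 6460 with the replicate block (4541 higher, 1919 lower), 12677 with scaling to the mitochondrially encoded protein genes (12665 higher, 12 lower, a scaling that sets those genes equal and raises all others), and 82 with no filter on low values (23 higher, 59 lower). Scaling to total reads gave 172 higher and 1258 lower. A minimum of 10 FPKM in 3 libraries gave 1751 higher and 160 lower among fewer genes, and pseudocount 0.1 with no filter gave 1385 lower. Leaving out 1 library or 1 experiment gave 0 to 2047 genes in total, 0 to 1372 higher and 0 to 675 lower. The count of 0 came from limma without experiment 2, where 2750 genes had an unadjusted p below 0.05 and the blocked fit called 5693. Median-ratio factors, limma-voom, pseudocount 0.1 and a 2-fold minimum kept the total and both directions within 1.5 times.

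For the blocked counts, alternatives were chosen after seeing the data. Scaling to total reads gave 1362 higher and 3824 lower, the stricter filter 4024 in total with 346 lower, and no filter 4291 lower. Limma-voom, median-ratio factors, pseudocount 0.1 and each experiment left out kept them within 1.5 times.

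Of the lists, 5 passed as higher and 4 as lower. With an estimated correlation 0 and 0 passed, with the replicate block as without it (the blocked form chosen after seeing the data). Fry, which does not compare a list with other genes, gave 0 higher and 3 lower, and the stricter filter 3 higher and 8 lower. The replicate block changed no list call. The planned edgeR fit was not run, since the deposited values are FPKM. Of the fits that use reads, limma-voom was run on the recovered reads.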

Other observations

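The genes of this paragraph lie outside the rule for named genes and were chosen after their values were seen. Rn7sk, Xist and Wsb1 were lower in HA, as Malat1 was. Rn7sk, the RNA of a nuclear regulator of transcription elongation, stood at 2.85, 1.31 and 0.911 FPKM in HA 1 to 3 and at 23.9, 30.4 and 33.0 in IgG 1 to 3 (limma log2 fold change -3.54 ± 0.31, adjusted p = 0.00247). Xist, the RNA that coats the inactive X chromosome, stood at 3.98, 0.162 and 0.329 against 82.5, 4.67 and 29.0 (-3.62 ± 0.91, adjusted p = 0.0393), though reads of its antisense partner cannot be separated. Wsb1 stood at 18.6, 19.9 and 12.2 against 139, 288.6 and 73.4 (-3.04 ± 0.48, adjusted p = 0.0213). IgG 3 stood apart at Trip11, with 2367 FPKM against 7.89 and 64.8 in the other IgG libraries and 2.08 to 22.0 in HA, and the gene did not pass (limma adjusted p = 0.118, and 0.00103 with the replicate block). The predicted gene Gm10800 held 22.7% of all FPKM in IgG 1, 0.119% in IgG 2 and 3.04% in IgG 3, and at most 0.152% in any HA library, without passing (limma adjusted p = 0.0509, and 0.000104 with the replicate block). Another predicted gene, Gm23935, which had a log2 fold change of 2.63 and did not pass (limma adjusted p = 0.176), held 19.4%, 6.14% and 5.82% in HA 1 to 3 and 2.38%, 1.47% and 3.68% in IgG 1 to 3.

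Of the tests in the next paragraphs, those of the other splits of the samples, of library scaling, of nuclear DNA and of the repeated sequence were chosen only after the result was seen. For the count of 1824 genes, the 10 possible splits of the 6 libraries are too few to give a share under 0.05; 1 of the 10, the real one, gave as many, and the highest of the others gave 0. Among the 4 splits that part all 3 pairs, the real one gave 6460 genes with the block and each of the others gave 0.

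The first pattern is the low level of mitochondrially encoded genes and of the nuclear and long noncoding RNAs in HA. A scaling error moves all genes of a library alike. The higher of the 2 list medians lay at least 1.55 below the median of all genes on the log2 scale (-1.552). Scaling can hardly change this distance, so it does not account for the lists' position relative to other genes. For the same reason the test had to come out this way under each scaling. It does not show whether these RNAs were fewer in HA or the others more abundant. Scaling to the mitochondrially encoded protein genes gave 12665 higher and 12 lower genes. For the mitochondrially encoded genes the values argue against nuclear DNA in the IgG libraries: with no filter on level, 16 of 20 exceeded the 99th percentile of the excess of IgG over HA at receptor genes in all 3 experiments, with a median excess of 35.1, 41.3 and 80.9 FPKM against percentiles of 3.04, 0.394 and 0.836, while mitochondrial DNA was not tested. For the nuclear and long noncoding RNAs, nuclear DNA stays open, since 17 of the 37 in the table exceeded those percentiles (2 of 1204 receptors did). The 16 of 26 among measured ones are favoured by the filter on level. The nuclear and long noncoding RNAs lay lower than protein-coding genes of the same IgG level. Of 10000 matched lists, 0% had a median as low as -1.33 (the typical median of matched lists was 0.47). A candidate explanation is that RNA outside cytosolic ribosomes is held less by the anti-HA precipitation. Where the members of the noncoding list lie in the cell was not tested, and it also holds long noncoding RNAs such as Gas5 and Snhg20. Other nonspecific capture by anti-IgG was not tested either, and input RNA was not analysed here.

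The second pattern is the rise of 5 lists and the low position of zinc finger genes. At camera's preset correlation, transcript length is argued against as the whole cause, since with the length trend removed in each library 6 of the 6 lists still passed in the blocked fit. Their medians became 0.54 for translation factors, 0.51 for cytosolic ribosomal proteins, 0.87 for the respiratory chain, 0.83 for the proteasome, 0.80 for mitochondrial ribosomal proteins and -0.33 for zinc finger genes, against 0.05 for all genes. This correction also made the immediate early list pass as lower (adjusted p = 0.00043, camera) and the astrocyte list as higher (adjusted p = 0.0345, and 0.0626 without the block). With the trend on mean level removed, 4 of the 6 still passed, but the distance of each list's median from that of all genes, which went from 0.27 to 0.07, became smaller. The median went from 1.21 (quartiles 0.91 and 1.49) to 0.29 (0.02 and 0.53) for the respiratory chain (adjusted p = 0.0160), from 1.28 (0.98 and 1.53) to 0.40 (-0.04 and 0.64) for the proteasome (adjusted p = 0.0175), from 1.11 (0.91 and 1.37) to 0.52 (0.24 and 0.81) for mitochondrial ribosomal proteins (adjusted p = 2.92e-06) and from -0.12 (-0.46 and 0.23) to -0.09 (-0.44 and 0.22) for zinc finger genes (adjusted p = 0.0240). The lists that no longer passed were cytosolic ribosomal proteins, from 0.92 (0.46 and 1.24) to -0.09 (-0.57 and 0.26), and translation factors, from 0.88 (0.47 and 1.25) to 0.02 (-0.50 and 0.45), because their difference from other genes was gone. The mean level was over all 6 libraries, HA included, so removing its trend can also remove part of a rise in HA itself. The test therefore cannot decide how much of the pattern is due to level. Expression level stays open as a cause, in part or whole, for these lists. In the blocked fit the same correction made the P-body (adjusted p = 0.0013), immediate early (adjusted p = 0.0013), G2 and M phase (adjusted p = 0.0055) and stem cell (adjusted p = 0.0350) lists pass as lower, and ependymal and histone genes as higher (adjusted p = 0.0160 and 0.0256, camera). Without the block the stem cell and histone lists did not pass (adjusted p = 0.0513 and 0.175), and the other 4 did. All list calls in this paragraph used the preset correlation, and an estimated one was not run with a trend removed. With no trend removed, an estimated correlation left none of the 6 lists past the threshold in the blocked fit (camera adjusted p from 0.732 to 0.871). Whether the RNAs of the 5 higher lists are more heavily loaded with ribosomes was not tested.

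The third pattern is the parallel rise of Lars2, Mir6236 and Mir6240, which resembles that of the predicted genes Gm15564 (limma adjusted p = 0.0369) and Gm23935 (adjusted p = 0.176, not past the threshold). If all 5 drew reads from 1 repeated sequence, such as a fragment of ribosomal RNA, their ratios would be nearly constant across libraries. The median SD of their log2 ratios was 0.326, and 16.45% of 10000 random sets of 5 other genes higher in HA had ratios as even. Those sets came from genes past the threshold, a choice that favours small spread and so even ratios. The test therefore cannot decide for or against a single shared source. At all 5 loci HA 1 held the highest value and IgG 2 the lowest. A shared repeat, separate repeats and the genes' own transcripts stay open, and no biological explanation was tested.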
